A study of Mus musculus with 3 samples.

How the data were processed

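Polyadenylated RNA of the mouse pancreatic cancer cell line KPC78 was sequenced in 3 libraries, replicates 1 to 3 of 1 group. Per the labels' protocols, total RNA was extracted with a column kit, mRNA was enriched with oligo-dT and libraries were made with Illumina TruSeq chemistry and a substituted PCR enzyme. The replicates are called biological in the series' design text, which does not say how the cultures were separated.

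The authors deposited a table of TPM per gene symbol, a share of transcripts scaled to a fixed total, made with kallisto, per the file headers. The submitters' processing notes name bcl2fastq 2.19, kallisto 0.44.0 and the genome build GRCm38.p6. The annotation release and the way transcripts were summed to genes are not given in the sources used here. Kallisto assigns reads to transcripts by pseudoalignment, so reads shared between a gene and its pseudogenes or paralogs are split by the model. TPM is corrected for transcript length, so genes can be compared within a library, while the read depth cannot be recovered and no counting intervals are given. The libraries summed to 999728, 999776 and 999741 TPM. A second, short table of the authors holds 3 columns whose names match no sample label. They are headed KPC cont with a running number, and the sheet lists integrin-named genes with Ccn1 and Ccn2. Its values were identical to those of the main table for the same genes, so it added no measurement and was not used. The sample labels do not call these libraries controls.

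Library columns were matched to samples by library name. A gene is called detected at or above 1 TPM in every library. Means and SDs are over n = 3. For 51 pairs of genes the log2 ratio of (TPM + 1) was taken in each library, and the mean ratio was tested against 0 with limma 3.58.1 in R 4.3.3 (intercept model, empirical Bayes spread over the pairs, two-sided, Benjamini-Hochberg adjustment over the 50 pairs tested, threshold 0.05). The pseudocount of 1 TPM understates ratios to genes near 0. Fold values are means of the TPM ratio per library and are given only where both genes were detected. An exact sign-flip test of 3 libraries cannot go below p = 0.25, so it was not used for calls. Pairs with both means below 1 TPM were not tested. For 25 lists of genes (319 symbols, 5 of them alternative names absent from the table) the share of detected members was compared with all other genes by a two-sided Fisher's exact test in scipy 1.17.1, adjusted over the 25 lists. Many symbols of the table are non-coding genes or pseudogenes, so each list was also compared with the 19527 symbols annotated as protein-coding in GENCODE M21, a choice made after the data were seen. Genes of a list are not independent replicates, and lists overlap.

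The lists, pairs, thresholds and the rule for named genes were fixed before the data were examined. The rule names every integrin subunit, the genes of the described pairs, the 4 detected members with the highest mean of every other list, the 10 genes with the highest mean TPM and the 5 with the largest coefficient of variation among genes with a mean of at least 10 TPM. A few genes that the rule would name are not reported here. Other genes named in the text were chosen after their values were seen, among them undetected list members such as the claudins and Esrp1. Coordinates and transcript lengths came from GENCODE M21 (GRCm38), matched by symbol for 32346 of the 35764 symbols. Transcript length and GC content were those of the longest protein-coding transcript, found for 95.2% of the genes with a mean of at least 10 TPM.

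The pair test was tested on simulated data with the real spreads of the 50 pairs, of which 20 were given a true ratio. It recovered 83.5% of pairs with a true log2 ratio of 0.25 and 12.7% of those with 0.1, and called 1.77% and 0.7% of the unchanged pairs. The list test, run on 35764 genes, called 99.8% of lists of 18 genes simulated at 90% detected and 1.18% of lists at the background share. The simulated lists were drawn from all symbols, of which 32.6% were detected. The rate of false calls does not carry over to lists of protein-coding genes, of which about 55.4% were detected. Alternatives were pseudocounts of 0.1 and 5, detection minimums of 0.5 and 5 TPM, detection by the mean, no filter on low pairs, a spread taken from 2000 random pairs, other backgrounds for the lists, geometric means, TPM rescaled without mitochondrial and ribosomal protein genes, and leaving out each replicate. For shares and for rescaling, ribosomal protein genes were picked by symbol, 405 in all, including pseudogenes whose symbols end in -ps and a number. Python 3.11.15 and pandas 2.3.3 were used.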

Results

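RNA was sequenced from KPC78, a mouse pancreatic ductal adenocarcinoma cell line labelled wild type. The series held 1 group of 3 libraries, described as biological replicates, and its stated purpose was to measure which integrin subunits these cells express. No treated or control group was part of the samples, so the comparisons were made between genes inside each library. Expression was given as TPM, a length-corrected share of transcripts. Each library listed 35764 gene symbols and summed to between 999728 and 999776 TPM. Genes at or above 1 TPM numbered 12078, 11938 and 12045 in replicates 1, 2 and 3, and 11665 genes reached that level in all 3 libraries and are called detected. The number of reads behind each library is not given in the table, so precision is stated from the replicates.

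Integrins are receptors made of 1 alpha and 1 beta chain that bind extracellular matrix. Itgb1 and Itgb5 were the most abundant beta chains of KPC78 cells, with 399 ± 12.4 TPM (SD, n = 3) for Itgb1 and 390 ± 11.9 TPM (SD, n = 3) for Itgb5. Together they made up 92.2% ± 0.41 (SD, n = 3) of the summed TPM of the 8 beta subunits, with 45.5% ± 0.26 from Itgb5 alone. Among alpha chains, Itga6 reached 147 ± 12 TPM and Itga3 120 ± 9.05 TPM (SD, n = 3), both laminin-binding subunits. Itgav, the alpha chain of the alpha-v beta-5 integrin, followed with 53.1 ± 2.37 TPM (SD, n = 3). Of 26 subunits, 13 were detected, namely 8 of 18 alpha and 5 of 8 beta chains. Neither share passed against all other genes (adjusted p = 0.38 and 0.16) or against protein-coding genes (0.46 and 0.84, Fisher's exact test). The beta partners of alpha-v and the leukocyte and platelet subunits did not pass either (adjusted p = 0.38 and 0.79 against all genes, Fisher's exact test).

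The other detected alpha subunits were Itga7 with 16.7 ± 1.40 TPM, Itga5 with 13.0 ± 0.72 TPM, Itga2b with 3.05 ± 0.76 TPM, Itga2 with 2.71 ± 0.62 TPM and Itga10 with 2.66 ± 0.16 TPM (SD, n = 3). Itga5 encodes the partner of beta-1 in the classical fibronectin receptor. The other detected beta subunits were Itgb4 with 52.8 ± 4.92 TPM, the hemidesmosomal partner of alpha-6, Itgb3 with 10.3 ± 0.25 TPM and Itgb7 with 2.74 ± 1.02 TPM (SD, n = 3). Itgb7 varied most among the detected subunits, with values of 1.57, 3.16 and 3.49 TPM. Below 1 TPM were Itga1 at 0.53 TPM, Itgae at 0.27 TPM, Itga4 and Itga9 at 0.20 TPM each, Itga8 at 0.15 TPM, Itgad at 0.059 TPM, Itgam at 0.028 TPM, Itga11 at 0.017 TPM and Itgal at 0.0033 TPM in the mean. Some of these means rested on 1 library: without replicate 2, Itga8 stood at 0.055 TPM, Itga9 at 0.12 TPM and Itgad at 0.089 TPM, and without replicate 3, Itgad stood at 0.0054 TPM and Itgal was listed at 0. Itgax, a leukocyte subunit, was listed at 0 in every library. Of the 9 leukocyte and platelet subunits, 2 were detected, Itga2b and Itgb7, while Itgb2, the common beta chain of the leukocyte integrins, stood at 0.33 ± 0.075 TPM (SD, n = 3).

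**Figure D1:**
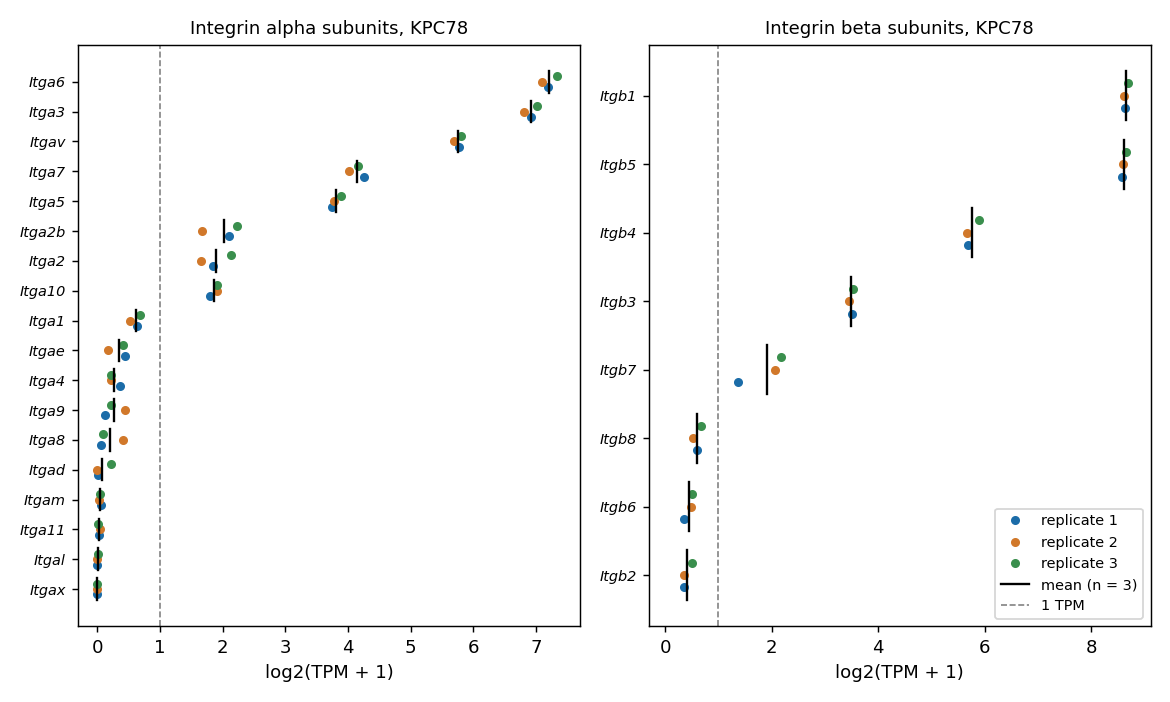
Expression of the 18 alpha (left) and 8 beta (right) integrin subunits in KPC78 cells, as log2(TPM + 1) on the horizontal axis. Each dot is 1 library, the black bar is the mean of n = 3 and the dashed line marks 1 TPM; Itgb1 and Itgb5 lie together at 399 and 390 TPM in the mean, and Itgb3 lies at 10.3 TPM.

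The title of the series names the alpha-v beta-5 integrin, so Itgb5 was compared with the other beta chains that can pair with alpha-v. Itgb5 was 37.9 ± 0.92-fold (SD, n = 3) above Itgb3 in TPM. On the log2(TPM + 1) scale the log2 ratio was 5.11 with a standard error of 0.034 (adjusted p = 1.30e-09, limma). Itgb6 and Itgb8, chains of integrins known to activate latent TGF-beta, stood at 0.36 ± 0.069 and 0.51 ± 0.074 TPM (SD, n = 3). The log2 ratio of Itgb5 was 8.16 to Itgb6 and 8.02 to Itgb8 on the log2(TPM + 1) scale (adjusted p = 3.65e-10 and 3.20e-10, limma). Itgb5 and Itgb1 could not be told apart by this test, with a log2 ratio of -0.03 and a 95% confidence interval from -0.12 to 0.05 (adjusted p = 0.33, limma). Itgb5 was the lower of the pair in 3 of 3 libraries, and the SD of the log2 ratio between libraries was 0.012. The test used a standard error of 0.032, drawn partly from the spread of the other pairs. Itgb5 was also 7.40 ± 0.44-fold above Itgb4 (adjusted p = 3.74e-08, limma). Itgb6 and Itgb8 were not compared with each other because both had a mean below 1 TPM.

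Itgb5 exceeded its only known alpha partner, Itgav, 7.35 ± 0.24-fold (SD, n = 3; adjusted p = 1.71e-08, limma). Itgav was in turn 2.25 ± 0.074-fold below Itga3 and 2.77 ± 0.11-fold below Itga6 (adjusted p = 7.21e-07 and 3.20e-07, limma), and 4.09 ± 0.20-fold above Itga5 (adjusted p = 1.01e-07, limma). Itga6 was 2.79 ± 0.096-fold above its partner Itgb4 (adjusted p = 2.52e-07, limma). Summed over all subunits, beta chains reached 855 ± 30.0 TPM and alpha chains 359.7 ± 26.1 TPM (SD, n = 3). In GENCODE M21 coordinates on GRCm38, Itgb5 spans 33829665 to 33949338 on the plus strand of chromosome 16 and Itgav spans 83724397 to 83806916 on the plus strand of chromosome 2. Itgb1 spans 128685654 to 128733200 on chromosome 8, Itgb3 104608000 to 104670476 on chromosome 11, Itgb6 60598292 to 60722643 on chromosome 2 and Itgb8 119158022 to 119238802 on chromosome 12. All 6 are annotated as protein-coding, and the values are listed per gene symbol, not per exon or UTR. These p-values rest on a spread between libraries that is partly shared over the 50 tested pairs. They leave out any bias of the TPM estimate of one gene against another. Of 51 pairs fixed in advance 50 were tested, and 49 passed an adjusted p of 0.05.

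Ligands of alpha-v integrins were led by Spp1 (osteopontin), with 8790 ± 381 TPM (SD, n = 3), the third most abundant of all genes in the mean. Thbs1, a matrix glycoprotein known to activate latent TGF-beta, reached 533 ± 25.9 TPM, Fn1 (fibronectin) 193 ± 28.2 TPM and Npnt (nephronectin) 190 ± 7.88 TPM (SD, n = 3). Vtn (vitronectin), a classical ligand of alpha-v beta-5, stood at 0.16 ± 0.096 TPM (SD, n = 3). Spp1 was 46.0 ± 5.81-fold above Fn1 (adjusted p = 1.86e-08, limma), and Fn1 exceeded Vtn by a log2 ratio of 7.39 on the log2(TPM + 1) scale (adjusted p = 1.97e-09, limma). Tnc was 6.07 ± 0.27-fold below Fn1 (adjusted p = 3.74e-08, limma). Among 18 ligand genes, 11 were detected, or 61.1%, against 32.6% of the other genes (two-sided Fisher's exact test, adjusted p = 0.039). Against protein-coding genes alone this difference did not pass (adjusted p = 0.85).

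The TGF-beta ligand Tgfb1 was present at 163 ± 8.31 TPM, Tgfb3 at 36.2 ± 1.31 TPM and Tgfb2 at 8.95 ± 0.22 TPM (SD, n = 3). Tgfb1 was 4.51 ± 0.12-fold above Tgfb3 and 18.3 ± 0.55-fold above Tgfb2 (adjusted p = 4.26e-08 and 3.59e-09, limma). The latent TGF-beta binding proteins, which tether the latent cytokine to matrix, were led by Ltbp1 at 176 ± 9.94 TPM, followed by Ltbp3 at 118 ± 9.14 TPM and Ltbp4 at 51.3 ± 5.04 TPM (SD, n = 3). Ltbp1 was 1.49 ± 0.031-fold above Ltbp3 (adjusted p = 1.45e-05, limma). Lrrc32, which holds latent TGF-beta on the surface of regulatory T cells and platelets, had a mean of 0.16 TPM, of which most came from replicate 1. In this list 8 of 11 genes were detected (adjusted p = 0.016 against all genes, 0.46 against protein-coding genes, Fisher's exact test). Of 11 genes known to release active TGF-beta from its latent form 10 were detected, led by Thbs1 and by the cathepsins Ctsl at 291 ± 10.1 TPM and Ctsd at 275 ± 4.51 TPM, with Plat at 70.6 ± 2.66 TPM (SD, n = 3; adjusted p = 0.00038 against all genes, 0.015 against genes above 0 in at least 1 library, 0.072 against protein-coding genes, Fisher's exact test). Mmp2 was listed at 0 in every library. The background of genes above 0 therefore left it out, and that test covered only the 10 detected genes.

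**Figure D2:**
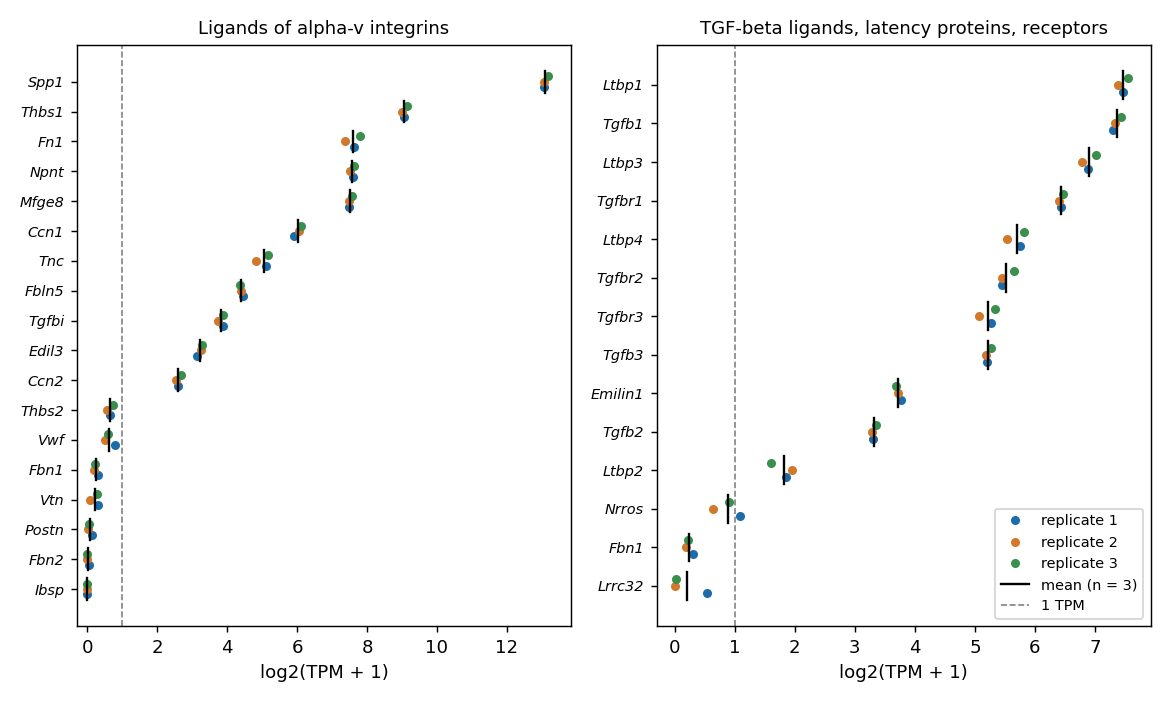
Ligands of alpha-v integrins (left) and TGF-beta ligands, latency proteins and receptors (right) in KPC78 cells, as log2(TPM + 1) on the horizontal axis. Dots are single libraries, black bars the mean of n = 3 and the dashed line 1 TPM; Spp1 lies at 8790 TPM in the mean and Vtn at 0.16 TPM.

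Of 17 genes in the list of TGF-beta receptors, SMADs and their regulators, 15 were detected (adjusted p = 1.64e-05 against all genes, 0.017 against protein-coding genes, Fisher's exact test). The list also holds inhibitors of the pathway, such as Ski and Smad7, and SMADs of the related BMP pathway, such as Smad1. The count therefore does not measure TGF-beta signalling. Tgfbr1, the type I receptor, stood at 85.6 ± 2.35 TPM, Smad3 at 83.8 ± 5.44 TPM, Ski at 64.1 ± 4.22 TPM and Smad4, the common partner of the signalling SMADs, at 54.1 ± 1.66 TPM (SD, n = 3). Tgfbr1 was 1.92 ± 0.11-fold above Tgfbr2 (adjusted p = 5.52e-06, limma), and Smad3 was 2.51 ± 0.050-fold above Smad2 (adjusted p = 2.77e-07, limma). Among known TGF-beta response genes 14 of 19 were detected, led by Cdkn2b at 286 ± 7.86 TPM, Fn1, Id1 at 183 ± 11.5 TPM and Id3 at 124 ± 7.30 TPM (SD, n = 3; adjusted p = 0.00092 against all genes, 0.24 against protein-coding genes, Fisher's exact test). The 5 that were not detected were Col1a1 at 0.53 TPM, Col1a2 at 0.056 TPM, Tagln at 0.21 TPM, Acta2 at 0.60 TPM and Itgb6. Col1a1, Acta2 and Tagln are also textbook genes of activated fibroblasts.

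The cytoplasmic adhesion machinery that links integrins to actin was detected for 23 of 28 genes (adjusted p = 9.59e-07 against all genes, 0.012 against protein-coding genes, Fisher's exact test). Actn4 stood at 345 ± 17.1 TPM, Actn1 at 204 ± 13.3 TPM, Vasp at 165 ± 7.42 TPM and Parva at 143 ± 3.34 TPM (SD, n = 3). Tln1, encoding the talin that activates integrins, was 21.1 ± 2.80-fold above Tln2 (adjusted p = 1.86e-08, limma). The kindlin gene Fermt2 stood at 44.2 ± 1.70 TPM and its epithelial relative Fermt1 at 0.74 ± 0.090 TPM (SD, n = 3; log2 ratio of Fermt1 to Fermt2 -4.70 on the log2(TPM + 1) scale, adjusted p = 2.43e-09, limma). Ptk2, the gene of focal adhesion kinase, was 1.74 ± 0.097-fold above Ptk2b (adjusted p = 1.09e-05, limma). Among genes of actin and YAP signalling 10 of 12 were detected, with Rhoa at 372 ± 7.60 TPM, Wwtr1 at 112 ± 4.57 TPM, Yap1 at 96.8 ± 6.26 TPM and Ccn1 at 64.1 ± 4.86 TPM (SD, n = 3; adjusted p = 0.0012 against all genes, 0.15 against protein-coding genes, Fisher's exact test). Basement membrane and collagen genes were detected for 16 of 21, with Sdc4 at 219 ± 8.01 TPM, Sdc1 at 119 ± 5.25 TPM, the laminin chain Lamb1 at 102 ± 7.83 TPM and Agrn at 98.5 ± 11.8 TPM (SD, n = 3; adjusted p = 0.00022 against all genes, 0.15 against protein-coding genes, Fisher's exact test).

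KPC78 cells expressed simple-epithelial keratins together with mesenchymal transcripts. Krt18 reached 1472 ± 31.0 TPM, Krt19 904 ± 65.4 TPM and Krt8 879 ± 23.6 TPM, and Cdh1 (E-cadherin) 54.0 ± 3.13 TPM (SD, n = 3). Vim (vimentin) stood at 4744 ± 116 TPM, S100a4 at 4446 ± 107 TPM and Sparc at 379 ± 9.43 TPM (SD, n = 3). Vim was 5.27 ± 0.31-fold above Krt19 and 88.0 ± 3.49-fold above Cdh1 (adjusted p = 7.15e-08 and 9.70e-10, limma). Epcam, an epithelial surface marker, stood at 0.16 ± 0.053 TPM (SD, n = 3). The tight junction genes Cldn3, Cldn4 and Cldn7 stood at 0.065, 0.030 and 0.058 TPM in the mean, with Cldn7 listed at 0 in replicates 1 and 3. Of other tight junction genes, Ocln stood at 0.96 TPM in the mean, while Tjp1 was detected at 52.7 ± 6.83 TPM (SD, n = 3). Cdh2 (N-cadherin) stood at 0.59 ± 0.057 TPM (SD, n = 3). Cdh1 exceeded Cdh2 by a log2 ratio of 5.11 on the log2(TPM + 1) scale (adjusted p = 1.16e-08, limma). Esrp1, a regulator of epithelial splicing, was listed at 0 in every library, while its relative Esrp2 was detected at 6.97 ± 0.85 TPM (SD, n = 3). In number, 9 of 18 epithelial genes (adjusted p = 0.17) and 11 of 14 mesenchymal genes (adjusted p = 0.0014) were detected, tested by Fisher's exact test against all genes, and neither passed against protein-coding genes (adjusted p = 0.77 and 0.18). The transcription factor gene Zeb1 was 2.22 ± 0.11-fold above Zeb2 (adjusted p = 1.95e-06, limma) and Snai2 was 1.83 ± 0.15-fold above Snai1 (adjusted p = 2.23e-05, limma).

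**Figure D3:**
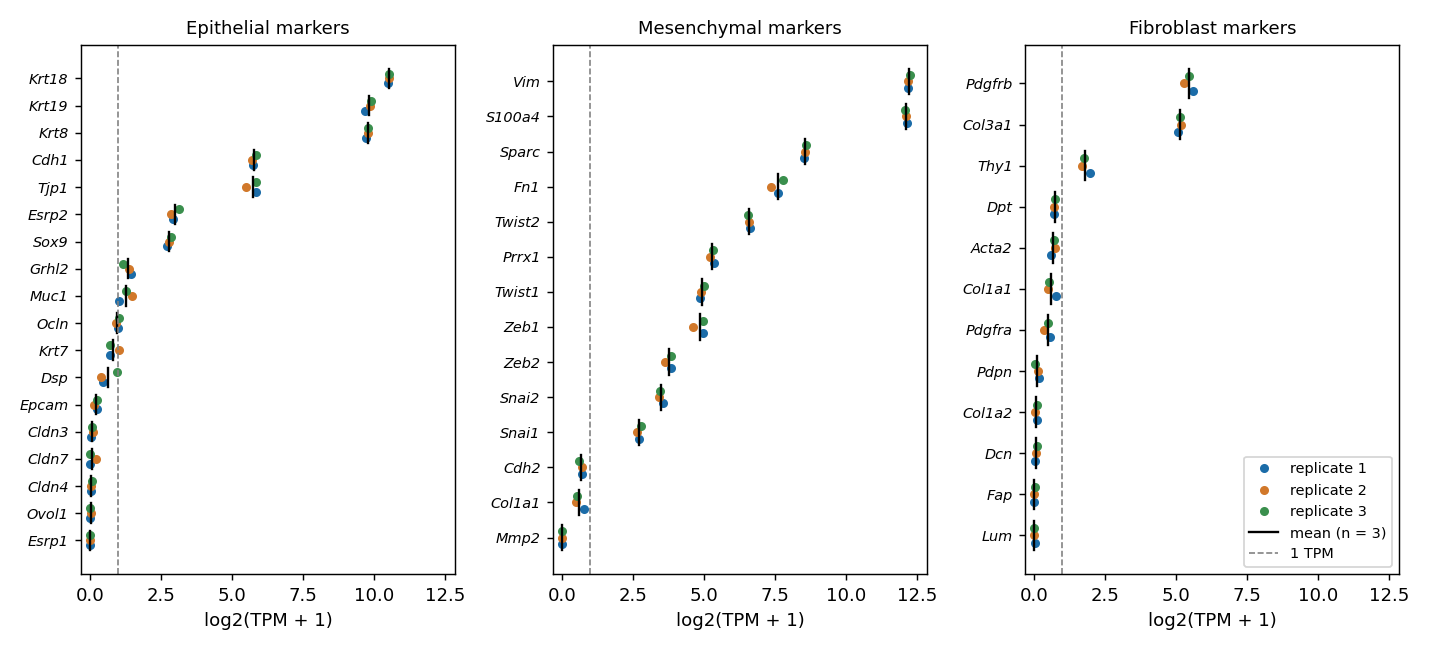
Epithelial (left), mesenchymal (middle) and fibroblast (right) marker genes in KPC78 cells, as log2(TPM + 1) on horizontal axes of equal range. Dots are single libraries, black bars the mean of n = 3 and the dashed line 1 TPM; Vim lies at 4744 TPM in the mean, Krt18 at 1472 TPM and Epcam at 0.16 TPM.

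Pancreatic lineage genes of the classical tumour subtype were detected for 8 of 13, led by Foxa2 at 72.3 ± 0.98 TPM, Pdx1 at 49.3 ± 2.45 TPM, Ceacam1 at 16.4 ± 0.81 TPM and Lgals4 at 13.7 ± 0.96 TPM (SD, n = 3; adjusted p = 0.057 against all genes, 0.85 against protein-coding genes, Fisher's exact test). Of 10 basal or squamous genes 3 were detected, among them Lamb3 at 1.75 ± 0.44 TPM and Trp63 at 1.68 ± 0.053 TPM (SD, n = 3; adjusted p = 1.00 against all genes, 0.19 against protein-coding genes, Fisher's exact test). Markers of other cell types of the pancreas or tumour were mostly below 1 TPM. None of 10 endocrine and none of 10 endothelial markers was detected (adjusted p = 0.057 each against all genes, 0.0019 each against protein-coding genes, Fisher's exact test). Of 14 leukocyte markers 1 was detected, Cd68 at 2.43 ± 0.85 TPM (SD, n = 3; adjusted p = 0.067 against all genes, 0.0019 against protein-coding genes, Fisher's exact test). Of 11 acinar markers 1 was detected, Cela1 at 9.55 ± 0.43 TPM (SD, n = 3; adjusted p = 0.16 against all genes, 0.012 against protein-coding genes, Fisher's exact test). Of 12 fibroblast markers 3 were detected, Pdgfrb at 42.8 ± 4.55 TPM, Col3a1 at 34.1 ± 1.53 TPM and Thy1 at 2.51 ± 0.36 TPM (SD, n = 3; adjusted p = 0.79 against all genes, 0.096 against protein-coding genes, Fisher's exact test).

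The replicates were close to each other. Across the 35764 genes, Pearson's r of log2(TPM + 1) was 0.9971, 0.9974 and 0.9972 and Spearman's rho 0.938, 0.940 and 0.939 for replicates 1 and 2, 1 and 3, and 2 and 3, where genes are not independent replicates. No gene above 0 had an identical value in any 2 libraries. The coefficient of variation of the 8502 genes with a mean of at least 10 TPM had a median of 5.29%. The most abundant gene was the elongation factor gene Eef1a1, at 15994 ± 401 TPM (SD, n = 3). Beside Spp1, the other genes of highest mean were mitochondrial and ribosomal protein genes and S100a6, with mt-Atp8 at 11442 ± 836 TPM, mt-Co3 at 7443 ± 162 TPM, mt-Atp6 at 6882 ± 239 TPM, Rpl23a at 6858 ± 224 TPM, S100a6 at 6771 ± 235 TPM, Rplp1 at 6705 ± 568 TPM and Rpl26 at 5550 ± 271 TPM (SD, n = 3). The 5 most variable genes of at least 10 TPM were Gm36718, Gm43110, Gm48789, Gm13378 and Gm48525, with coefficients of variation from 66.7% to 86.7%. The last 4 are annotated as processed pseudogenes, whose reads can be shared with their parent genes, and Gm36718 was listed at 0 in replicate 2.

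Replicate 2 stood apart in a measurable way. Its deviation from the mean of the other libraries fell with transcript length, with Spearman's rho of -0.49 across 8093 genes, against 0.24 for replicate 1 and 0.38 for replicate 3. The 3 deviations of a gene sum to 0 by construction, so a trend in one library forces an opposite one over the others. Ribosomal protein genes, counted with their named pseudogenes, took 22.5% of its TPM, against 20.8% and 20.9% in replicates 1 and 3. Mitochondrial genes took 4.79%, against 5.49% and 5.14%. Among the integrin genes, Itgav stood at 50.5 TPM in replicate 2 and at 53.6 and 55.1 TPM in replicates 1 and 3, and Itgb5 at 384 TPM against 382 and 403 TPM. The low-expressed Itga2b stood at 2.20 TPM against 3.28 and 3.68 TPM, and Itga2 at 2.15 TPM against 2.60 and 3.37 TPM. Without replicate 2, the number of detected subunits was again 13 and 49 of the gene pairs passed.

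**Figure D4:**
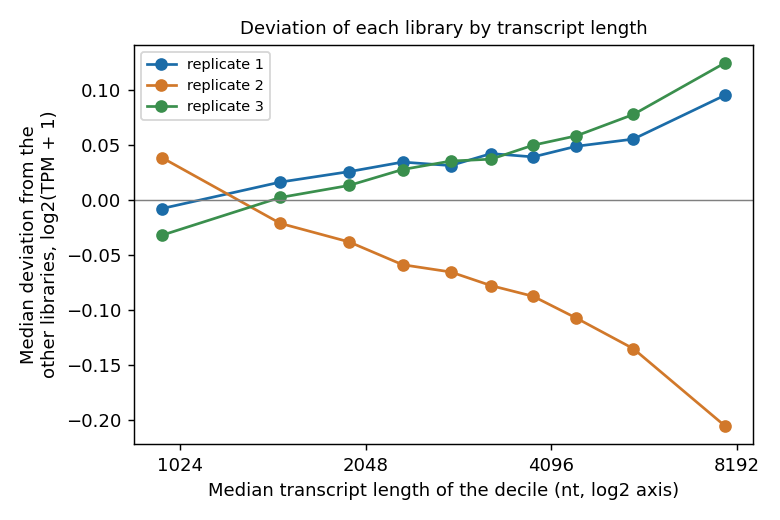
Median deviation of each library from the mean of the other libraries, in log2(TPM + 1), for 10 equal groups of genes by transcript length in nucleotides (log2 axis). Replicate 2 runs from 0.04 for the shortest genes to -0.21 for the longest, and replicates 1 and 3 run the other way, as they must in sum because the 3 deviations of a gene add up to 0.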

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

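No paired analysis was possible because the series has 1 group, and each gene ratio was already taken within a library. In all 7 alternatives of the pair test, including 3 that left out a replicate, the direction and call of each of the 50 tested pairs was the same, and 49 or 50 pairs passed. Itgb5 and Itgb1 stayed below the threshold throughout, with adjusted p from 0.31 to 0.59. The size of ratios to genes near 0 depended on the pseudocount: the log2 ratio of Itgb5 to Itgb6 was 9.72 with a pseudocount of 0.1 and 6.20 with 5. Detected integrin subunits numbered 13 under each alternative except a minimum of 5 TPM, which left 9. The mean of Itgb5 ranged from 383 to 393 TPM without 1 replicate and rose to 530 TPM when mitochondrial and ribosomal protein genes were left out of the total, a rescaling that raises every other gene alike. The number of lists past the threshold depended on the background and on the detection minimum. It was 13 against all genes, 8 against genes above 0 in at least 1 library, and 9 against protein-coding genes, a setting chosen after the data were seen. Against genes above 0, 6 of the 13 lists kept their call and 7 lost it, and the leukocyte and endothelial lists passed as detected less often (adjusted p = 0.022 and 0.0043). The 6 were those of the latent TGF-beta activators and the 5 that also kept it against protein-coding genes (TGF-beta receptors and SMADs, adhesion complex, KPC pathway, proliferation, and RNA quality and stress). For the activators, the undetected Mmp2 fell outside this background because it was at 0. Their call there rests on the 10 detected genes alone. Against protein-coding genes 8 lists lost their call, and 4 lists of other cell types passed as detected less often. With a minimum of 0.5 TPM 16 lists passed, adding the epithelial list (adjusted p = 0.038) and, as detected less often, the endocrine and endothelial lists (0.034 each), which also passed with detection by the mean (0.036 each), where 15 passed. With a minimum of 5 TPM 13 passed, the immune list losing its call (0.071) and the leukocyte list gaining one as detected less often (0.030). Leaving out a replicate gave 13 lists each time. Read depth is unknown, so values below 1 TPM cannot be given a counting error.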

Other observations

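All tests of explanations in this part were chosen after the result they bear on was seen. Genes of the KPC pathway list and of cell division were detected throughout: 19 of 19 KPC pathway genes and 14 of 14 proliferation genes (adjusted p = 1.41e-08 and 9.59e-07 against all genes, 0.00047 and 0.0020 against protein-coding genes, Fisher's exact test). Cdkn2a, the tumour suppressor locus, stood at 981 ± 15.4 TPM, Myc at 207 ± 5.10 TPM, Trp53 at 167 ± 0.87 TPM and Dusp6, a feedback phosphatase induced by ERK signalling, at 157 ± 6.76 TPM (SD, n = 3). Cdkn1a, a direct p53 target, stood at 2.34 ± 0.20 TPM and Mdm2, another, at 32.4 ± 1.69 TPM (SD, n = 3). Proliferation genes were led by Pcna at 175 ± 4.28 TPM, Top2a at 134 ± 11.2 TPM, Mcm6 at 133 ± 0.51 TPM and Cdk1 at 125 ± 5.31 TPM (SD, n = 3).

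Immune signalling genes were detected for 14 of 20 (adjusted p = 0.0024 against all genes, 0.36 against protein-coding genes, Fisher's exact test), with B2m at 898 ± 34.0 TPM, H2-D1 at 69.5 ± 1.60 TPM, the monocyte attractant Ccl2 at 67.5 ± 3.97 TPM and H2-K1 at 63.8 ± 6.47 TPM (SD, n = 3). Cd274 (PD-L1) stood at 1.06 ± 0.089 TPM (SD, n = 3) with 0.96 TPM in replicate 1. Of the RNA quality and stress genes 14 of 14 were detected, led by mt-Co1 at 4665 ± 633 TPM, mt-Nd1 at 3011 ± 277 TPM, mt-Cytb at 2493 ± 316 TPM and Junb at 86.7 ± 6.16 TPM (SD, n = 3; adjusted p = 9.59e-07 against all genes, Fisher's exact test).

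Keratins and vimentin in one culture, with Spp1 among the highest genes, could come from a mixture with stromal cells. Col1a1, Col1a2, Dcn and Lum, abundant in fibroblasts, had a median of 0.056 TPM. This argues against fibroblasts rich in these 4 transcripts as the source of 4744 TPM of Vim. The 4 genes were chosen after the values were seen. The list of 12 fibroblast markers fixed in advance had a median of 0.46 TPM, with Pdgfrb, Col3a1 and Thy1 detected. Macrophages, a known source of Spp1, would bring Lyz2, Csf1r, Adgre1, Tyrobp and Ptprc, whose median was 0.014 TPM. Cd68, left out of this set, was detected at 2.43 TPM. Whether single KPC78 cells hold both programmes, or epithelial-like and mesenchymal-like tumour cells coexist, stays open in bulk RNA, and Col3a1 and Pdgfrb at 34.1 and 42.8 TPM were not explained.

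Itgb5 lay 7.35-fold above Itgav, although beta-5 is known to pair with alpha-v alone. Longer transcripts had lower TPM across the 8093 genes, by 0.54 log2 units per doubling of length, and the longest coding transcript of Itgav has 7054 nt against 3282 nt in Itgb5. With that trend removed, 78.9% of the log2 difference was left, so the average trend covered only a part of it. The trend was taken over genes with a mean of at least 10 TPM and does not measure a bias of the estimate. A bias of the estimate particular to either gene stays open, transcript levels do not give protein levels, and no biological explanation was tested.

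The deviation of replicate 2 followed transcript length (Spearman's rho -0.49), and removing the trend lowered its SD across genes from 0.129 to 0.112 log2 units, against 0.107 to 0.104 in replicate 1 and 0.105 to 0.098 in replicate 3. GC content showed a correlation of 0.037 with the deviation of replicate 2, against -0.13 in replicate 1 and 0.078 in replicate 3 (Spearman's rho). This argues against a steady rise or fall with GC content in replicate 2. A dependence that rises and then falls would not show in this measure. A larger share taken by a few abundant genes would shift all other genes alike, but the shortest and longest groups of genes differed by 0.24 log2 units. Why length mattered more in this library, such as RNA integrity or fragment size, was not tested. Values of long genes such as Hspg2, at 33.5 TPM in replicate 2 and 45.1 and 47.3 TPM in replicates 1 and 3, may carry this trend (rho -0.49).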
